A study of Homo sapiens with 12 samples.

How the data were processed

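RNA of H1299 cells was measured on 12 two-colour Agilent expression arrays. Per the labels, the cells carried a transgene for wild-type BRG1 (BRG1-WT) or mutant BRG1 (BRG1-MUT) under a doxycycline-dependent promoter and were grown with or without doxycycline at 2 ng per microlitre for 6, 12 or 24 h. Each array set RNA of treated cells in one dye against RNA of untreated cells of the same line and time in the other dye. Per the labels, doxycycline RNA was in Cy5 on 9 arrays and in Cy3 on 3 arrays (BRG1-WT 12 h replicate 2, BRG1-MUT 24 h replicate 1 and BRG1-MUT 6 h replicate 3). Groups, times and dyes were taken from the labels alone. The labels number 6 of the 12 arrays, and the replicate numbers of the other 6 were assigned here to tell arrays apart.

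Per the file headers, the arrays were scanned on 3 slides of 4 arrays and read with Agilent Feature Extraction 9.5.3, and the probe coordinates are on hg17. The deposited intensity columns hold the mean pixel brightness of each spot and the median of its local background in the green (Cy3) and red (Cy5) channels, not normalized. Per the file headers, the deposited log10 ratio of red over green was detrended and dye-normalized by Feature Extraction, and per the same headers the other columns used are 0 or 1 flags for spots well above background, saturated or non-uniform. The authors' deposited value table holds log10 values with scale and direction unstated. Its columns were equal to the scanner files' log10 ratio on the 9 arrays labelled forward and to minus that ratio on the 3 arrays labelled swapped, and the median of every column was 0.

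Each array held 45015 spots, of which 43376 were not controls. The median signal per array was 227 to 338 in green over a background of 52 to 54.5, and 415 to 575 in red over a background of 70 to 73. Between 69.2% and 80.8% of spots were well above background in green and between 73.2% and 87.7% in red. The software marked 84 to 146 spots per array as outliers, which were left out, and 0 to 6 as saturated, which were kept. The number of arrays limits the precision of every value.

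Background was corrected with normexp (offset 50) and ratios were normalized within each array by loess with control spots given no weight, in limma 3.58.1 under R 4.3.3. Spots of a probe were averaged. Of 41000 probes, 23434 were named through an accession in the RefSeq gene table (GRCh38.p14, used for names alone), 2317 through a symbol and 1043 through a synonym, which gave 17519 distinct symbols, while 14206 kept the name in the files. A gene was represented by its brightest probe, and probes were kept when well above background in either channel on at least 2 arrays, which left 27132 genes in the BRG1-WT test. Arrays labelled swapped entered with the opposite sign. The limma model held the 6 line-by-time groups and a dye intercept for each gene, and the groups shared 1 estimate of the spread. The response of a line was the mean of its 6, 12 and 24 h coefficients. Adjusted p-values are Benjamini-Hochberg values from limma's moderated test with a threshold of 0.05, and log2 values are doxycycline over none with the model's SE. The labels do not say that replicate arrays came from separate cultures, so p-values measure only the spread between these arrays.

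A total of 27 gene lists, among them blood cell markers as another cell type, were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. Lists needed 4 measured members. The design, the lists, most of the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 largest rises and 12 largest falls past the threshold with 1 sign on every array of the line. For the difference between lines, every BRG1-WT time mean of the array ratios, with the dye effect left in, had to lie on the same side of every BRG1-MUT time mean. Where nothing passed, the 5 genes with the smallest p in each direction were named. The rule also took 3 genes per direction for each single time, 5 for each test over times and up to 4 members per list with the smallest p in BRG1-WT. Genes outside the rule are named as such.

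SMARCA4, the gene of BRG1, was read first as a check of the labels, and on 3 arrays it went against them. Fits without these 3 arrays (9 arrays, 2 residual degrees of freedom) and with their sign turned were therefore added after the data had been seen. Values below come from the fit of 9 arrays unless the text says otherwise. Counts of genes from the fits of all arrays as labelled and with turned signs are also given. List medians and most single values from these fits are not. In the 9 arrays, BRG1-WT 6 h, BRG1-WT 24 h and BRG1-MUT 12 h hold 1 array each, assumed to vary like the other groups. A fold written as at least a value set the mean of the brighter channel against the lowest signal among probes well above background, after loess and between-array quantile normalization of the average intensity.

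The steps were tested on simulated data of 27048 genes with 200 genes changed in BRG1-WT. With the layout of 9 arrays, 38.8% of changes of 0.5 on the log2 scale, 74.6% of changes of 1 and 95.5% of changes of 2 were called in BRG1-WT with 0 false calls. For the difference between lines the same layout gave 0%, 59.7% and 93.9% with 1 false call. The simulation drew independent normal errors and kept each change constant over the times. It held no response in BRG1-MUT and no slide effect, so its shares and false calls need not carry over to the real arrays. Alternatives covered background correction, normalization, the filter, the probe rule, the dye intercept, slide, replicate number, array weights, the weighting of times, list tests, a 1.5-fold limit and each array left out. Figures were drawn with matplotlib 3.10.9. Some genes picked by the naming rule are not reported here.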

Results

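H1299 is a human non-small cell lung cancer line that lacks BRG1, the ATPase of the SWI/SNF chromatin remodelling complex encoded by SMARCA4. The design compared gene expression with and without doxycycline, at the same time, in cells with a doxycycline-dependent BRG1-WT or BRG1-MUT transgene. The labels do not name the mutation. BRG1-WT was measured on 5 arrays (1 at 6 h, 2 at 12 h and 2 at 24 h) and BRG1-MUT on 7 (3 at 6 h, 2 at 12 h and 2 at 24 h). No array held cells without a transgene.

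SMARCA4 RNA was higher with doxycycline on 9 of the 12 arrays, in both lines. The brightest SMARCA4 probe (chromosome 19, 11030037 to 11030520, hg17) gave log2 ratios of 1.93 ± 0.31 (SD, n = 9) there. On these arrays its raw signal without doxycycline was 2471 to 11716, well above background, so the probe also gave signal in untreated cells. A probe at 10999475 to 10999534 gave 1.86 ± 0.37 (SD, n = 9). A probe nearer the 3′ end of the gene (11033673 to 11033732) gave 0.22 ± 0.48 (SD, n = 9). On the arrays labelled BRG1-WT 24 h replicate 1, BRG1-MUT 12 h replicate 1 and BRG1-MUT 6 h replicate 1, all on slide 1 and labelled with doxycycline in Cy5, the brightest probe gave -2.23 ± 0.19 (SD, n = 3). The probe at 10999475 gave -2.07 ± 0.24 (SD, n = 3) and the 3′ probe 0.12 ± 0.57 (SD, n = 3). Across genes other than SMARCA4, with the dye effect removed, the array labelled BRG1-WT 24 h replicate 1 correlated with replicate 2 at r = -0.437. The array labelled BRG1-MUT 12 h replicate 1 correlated with replicate 2 at r = -0.627. The array labelled BRG1-MUT 6 h replicate 1 correlated with replicates 2 and 3 at r = -0.374 and -0.655. The other replicate pairs gave 0.724 (BRG1-WT 12 h), 0.749 (BRG1-MUT 6 h) and 0.692 (BRG1-MUT 24 h). These pairs alone set the dye effect, so part of their agreement after its removal is built in. Before its removal they gave -0.338, -0.238 and 0.590. The BRG1-WT 24 h and BRG1-MUT 12 h pairs then gave -0.407 and -0.521. BRG1-MUT 6 h replicate 1 gave 0.458 with replicate 2 and -0.870 with replicate 3. Genes are not independent replicates in these correlations. Among the choices of sign for these 3 arrays, the median residual SD without SMARCA4 was lowest with all 3 turned (0.120). It was highest as labelled (0.178). These values argue against the labelled directions of the 3 arrays, while the cause of the conflict is not settled.

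**Figure D1:**
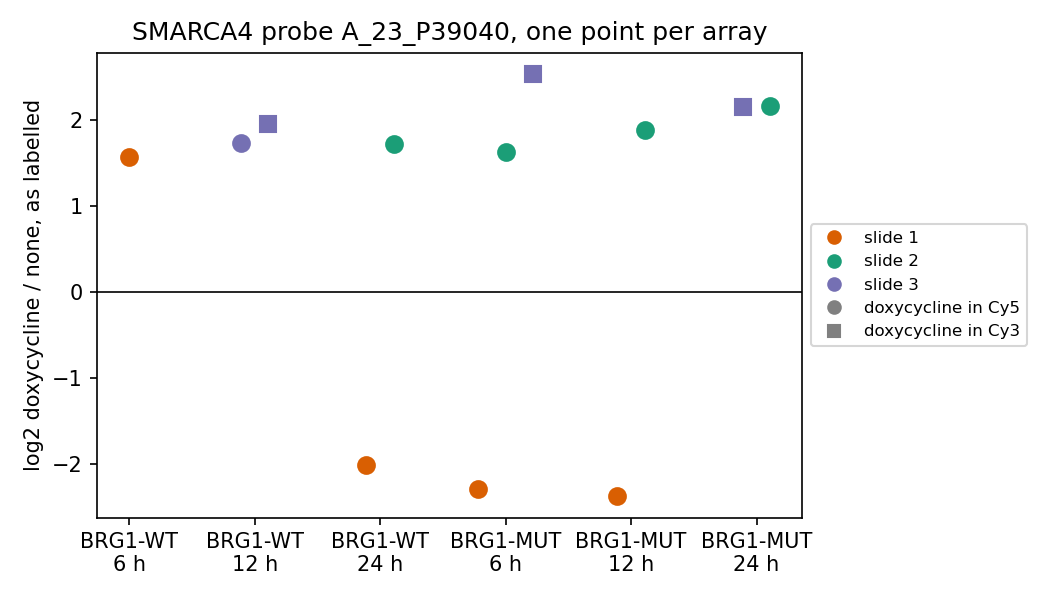
Each point is the log2 ratio of doxycycline over none as labelled (y axis) for the brightest SMARCA4 probe on 1 array, by group along the x axis, with slide as colour and the labelled dye as symbol. The 3 arrays of slide 1 described above lie between -2.38 and -2.01, and the other 9 lie between 1.58 and 2.54.

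With all 12 arrays as labelled, SMARCA4 was 1.498 in BRG1-WT (limma adjusted p = 1.00) and 1.12 in BRG1-MUT (adjusted p = 0.868), and neither passed. No gene passed limma's threshold. At an unadjusted p under 0.05, 236 genes were counted in BRG1-WT, 741 in BRG1-MUT and 521 for the difference between lines. Each count lies below what chance alone gives on average at that limit, with at least 27132 genes tested. The BRG1-WT genes with the smallest p, none of which passed, were JPH3 (0.32), NPR3 (0.27), IL4I1 (0.58), EDN1 (0.29) and EXPH5 (0.27) among those above 0. Below 0 they were PWAR5 (-0.26), ZDHHC14 (-0.30), CRCP (-0.27), SFPQ (-0.23) and CKS2 (-0.46). In BRG1-MUT they were PRKAG1 (0.33), RPS6 (0.29), RFPL2 (0.20), CLCN3 (0.19) and UFM1 (0.34), and SLC16A3 (-0.38), TEX19 (-0.32), SALL2 (-0.25), TRERF1 (-0.24) and KCNV1 (-0.18). For BRG1-WT minus BRG1-MUT they were SLC16A3 (0.61), TEX19 (0.63), SALL2 (0.48), ARHGEF40 (0.47) and EDN1 (0.42), and PTPDC1 (-0.44), PWAR5 (-0.27), HIPK3 (-0.38), SEPTIN14 (-0.35) and ZNF225 (-0.34). These values mix arrays that ran opposite to each other, and the comparisons below leave the 3 arrays out.

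In BRG1-WT cells GDF15, a stress-induced cytokine of the TGF-beta family, rose with doxycycline by 1.87 ± 0.085 on the log2 scale (SE, n = 4 arrays, adjusted p = 0.00112), or by 1.03 without the single 24 h array. TRIB3, a pseudokinase of the integrated stress response, rose by 1.82 ± 0.074 (adjusted p = 0.00101). SMARCA4 itself was higher by 1.84 ± 0.12 (adjusted p = 0.00426), a value that is not independent because the arrays were chosen on this gene. IL11, a cytokine of the interleukin-6 family, rose by 1.69 ± 0.072 (adjusted p = 0.00101), and EPAS1, which encodes HIF-2alpha, rose by 1.30 ± 0.14 (adjusted p = 0.015). LMNB1, which encodes lamin B1, fell by 1.05 ± 0.071 (adjusted p = 0.00426), or by 0.68 without the single 6 h array.

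The other largest rises in BRG1-WT were NUPR1 (1.74), DDIT4, an inhibitor of mTORC1 signalling (1.56), PCK2, the mitochondrial PEP carboxykinase (1.38), DDIT3, the transcription factor CHOP (1.32), the hair keratin KRT86 (1.26), the cystine transporter SLC7A11 (1.17) and LURAP1L (1.13). The other largest falls were BIRC3, an inhibitor of apoptosis (-0.91), the chaperone HSPA1A (-0.84, with a near-identical copy, so uncertain), NCEH1 (-0.84), the Mediator subunit MED13L (-0.83), the Notch target HES1 (-0.77), PBX2 (-0.68), BEST3 (-0.65) and FOS (-0.64). The related ANP32D, ANP32A and ANP32CP gave -0.71, -0.69 and -0.68 and are uncertain because their sequences are close. For MED13L and BEST3, 2 of 3 probes had the same sign.

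In all, 671 genes changed in BRG1-WT, 358 higher and 313 lower, and 172 of the 671 by at least 1.5-fold. With Agilent's own log ratios the split was 24 higher and 11 lower. With the sign of the 3 arrays turned, 3245 genes passed, among them 353 of the 358 higher and 294 of the 313 lower. ANP32D and PBX2 then missed the threshold (adjusted p = 0.0509 and 0.0895). The count was 4 without the dye intercept, 165 with slide as a block (without the BRG1-WT 6 h array), 22 without BRG1-WT 12 h replicate 2, 140 without replicate 1, 166 without the BRG1-WT 24 h array, 1360 without the 6 h array and 6830 without either BRG1-MUT 24 h array.

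Among the gene lists, 16 of the 26 amino acid and ER stress response genes rose in BRG1-WT and 0 fell (23 and 1 adjusted over the list alone), with a median of 0.65. Camera gave an adjusted p of 6.8e-26, against an adjusted p = 0.182 with an estimated correlation and 0.0118 by fry. The list's median lay between 0.52 and 0.88 on each of the 9 arrays. Of the heat shock genes 4 of 14 fell (median -0.28, 8 lower adjusted over the list alone), among them HSPA8 (-0.47 ± 0.062), DNAJA1 (-0.46 ± 0.075) and the mitochondrial co-chaperone HSPE1 (-0.42 ± 0.073). Camera gave 2.7e-05 for the list, with an adjusted p = 0.352 with an estimated correlation. Mitotic genes had a median of -0.21, with 1 of 30 lower, the survivin gene BIRC5 (-0.37 ± 0.064), and 12 lower adjusted over the list alone (camera adjusted p = 1.2e-09, adjusted p = 0.352 with an estimated correlation). The median of MYC target genes was -0.15, with 3 of 40 lower, GNL3 (-0.35), NOP16 (-0.44) and HSPE1, and 9 adjusted over the list alone (camera adjusted p = 6.3e-08, adjusted p = 0.400 with an estimated correlation). Without the single 24 h array no member of the heat shock, mitotic and MYC target lists passed limma's threshold (HSPA8 -0.33, DNAJA1 -0.42, GNL3 -0.33 and NOP16 -0.31), while camera still gave 9.0e-05, 1.1e-08 and 4.0e-08. Without the single 6 h array 3 mitotic genes were lower and the MYC target median was -0.092.

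Metallothioneins had a median of 0.32 in BRG1-WT, with 2 of 10 higher, MT1X (0.33) and MT1A (0.35), and 7 adjusted over the list alone (camera adjusted p = 2.7e-05, adjusted p = 0.400 with an estimated correlation). The count was 7 without the single 6 h array and none passed limma's threshold without the single 24 h array. Their near-identical sequences leave single members uncertain. Immediate early genes had a median of -0.13, with 2 of 24 higher and 3 lower (2 and 6 adjusted over the list alone). EGR1 fell by 0.80 ± 0.10 and DUSP1 by 0.37 ± 0.059, while ATF3, also a target of the stress response, rose by 0.49 ± 0.070. Camera gave 0.0178 for the list, with an adjusted p = 0.400 with an estimated correlation, and 0.0734 without the single 24 h array and 0.149 without the 6 h array. Mesenchymal and matrix genes had a median of 0.05, with 3 of 29 higher and 0 lower (4 and 1 adjusted over the list alone), among them SPARC (0.64 ± 0.070) and TAGLN (0.47 ± 0.066), at a camera adjusted p of 0.0308 and an adjusted p = 0.400 with an estimated correlation. S-phase genes (median -0.095, 0 of 30 passing, 0 adjusted over the list alone), cholesterol synthesis genes (median -0.063, 0 of 20, 4 lower adjusted over the list alone) and interferon-stimulated genes (median 0.072, 1 of 28 higher, IRF7 at 0.35; 1 higher and 1 lower adjusted over the list alone) gave camera adjusted p of 0.000938, 0.0214 and 0.0467. The adjusted p with an estimated correlation was 0.352 for S-phase genes and 0.400 for the cholesterol and interferon lists. Without the single 24 h array camera gave 0.0776, 0.712 and 0.286 for these 3 lists and 0.242 for mesenchymal and matrix genes. EGR1 was then -0.35, HSPE1 -0.19, BIRC5 -0.17, TAGLN 0.22 and SPARC 0.45, and none of the 5 passed. No mesenchymal or interferon-stimulated gene passed limma's threshold there, and 1 immediate early gene was higher and 1 lower. Without the single 6 h array the cholesterol synthesis median was -0.17 with 4 lower, and the immediate early median -0.083. Blood cell markers, as another cell type, had a median of 0.03 with 0 of 13 passing.

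In BRG1-MUT cells TRIB3 had the largest rise with doxycycline, by 2.27 ± 0.061 (SE, n = 5 arrays, adjusted p = 0.000118). SMARCA4 was higher by 2.11 ± 0.10 (adjusted p = 0.000434, not independent as above). DDIT4 rose by 2.00 ± 0.055 (adjusted p = 0.000118), and ASNS, which makes asparagine, by 1.57 ± 0.068 (adjusted p = 0.000267). The largest fall was that of KNL1, a kinetochore scaffold, by 1.24 ± 0.095 (adjusted p = 0.00239), followed by ITGA9, an integrin subunit, by 0.86 ± 0.068 (adjusted p = 0.00247). Without the single 12 h array KNL1 was -0.72 and ITGA9 -0.84.

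The other largest rises in BRG1-MUT were PCK2 (1.63), SLC7A11 (1.52), JDP2 (1.49), the secreted glycoprotein STC2 (1.45), DDIT3 (1.44), SESN2 (1.44), GDF15 (1.36) and the mitochondrial folate enzyme ALDH1L2 (1.28). The other largest falls were BIRC3 (-0.83), BNC2 (-0.78, 2 of 4 probes of the same sign), the potassium channel KCNJ2 (-0.77), DNAJA1 (-0.76), SERPINB7 (-0.74), SKIDA1 (-0.74), B3GNT9 (-0.73), the CDK inhibitor CDKN2C (-0.73), EOGT (-0.68, and -0.41 with an adjusted p = 0.0795 without the 12 h array) and the cell cycle phosphatase CDC25A (-0.68). A total of 4638 genes changed, 2649 higher and 1989 lower, and 324 by at least 1.5-fold. With turned signs 7475 passed, among them 2564 of the 2649 and 1923 of the 1989. The count was 68 without the dye intercept, 2441 with slide as a block (without the BRG1-WT 6 h array) and 2441 without either BRG1-WT 12 h array, 1453 without BRG1-MUT 6 h replicate 3, 10715 without BRG1-MUT 24 h replicate 2 and 12081 without replicate 1.

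Of the amino acid and ER stress response genes 21 of 26 rose in BRG1-MUT and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.78. Camera gave 3.9e-18, with an adjusted p = 0.260 with an estimated correlation and 0.00607 by fry. Metallothioneins had a median of 0.49, with 7 of 10 higher (7 adjusted over the list alone; camera adjusted p = 1.6e-05, adjusted p = 0.443 with an estimated correlation). Of the heat shock genes 9 of 14 fell (median -0.31, 10 lower adjusted over the list alone; camera adjusted p = 1.6e-05, adjusted p = 0.307 with an estimated correlation), among them HSPE1 (-0.55 ± 0.061) and HSPA8 (-0.42 ± 0.051). Mitotic genes (median -0.21, 13 of 30 lower, 17 adjusted over the list alone) included BIRC5 (-0.48 ± 0.053), ASPM (-0.36 ± 0.062) and BUB1 (-0.30 ± 0.049). S-phase genes (median -0.16, 10 of 30 lower, 14 adjusted over the list alone) included the polymerase clamp PCNA (-0.41 ± 0.051) and MCM3 (-0.31 ± 0.061). Camera gave 2.2e-07 for mitotic and 3.9e-05 for S-phase genes, each with an adjusted p = 0.307 with an estimated correlation.

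Cholesterol synthesis genes had a median of -0.20 in BRG1-MUT, with 1 of 20 higher and 9 lower (1 and 13 adjusted over the list alone), among them IDI1 (-0.52 ± 0.057). Camera gave 3.9e-05 for them, with an adjusted p = 0.324 with an estimated correlation. Immediate early genes had a median of 0.17, with 8 of 24 higher and 1 lower (10 and 1 adjusted over the list alone). ATF3 rose by 1.03 ± 0.058, EGR1 by 0.48 ± 0.084 and FOS by 0.23 ± 0.060, at a camera adjusted p of 0.00354 and an adjusted p = 0.324 with an estimated correlation. With turned signs FOS was 0.13 and missed limma's threshold (adjusted p = 0.184). Without the single 12 h array the list's median was 0.080 with 3 higher and 1 lower (camera adjusted p = 0.311), EGR1 was 0.016 (adjusted p = 0.936) and FOS -0.056 (adjusted p = 0.629). The MYC/MAX network (median 0.05, 4 of 13 higher, 4 adjusted over the list alone) included MNT (0.61 ± 0.062) and MXD4 (0.26 ± 0.054), at a camera adjusted p of 0.0378 and an adjusted p = 0.565 with an estimated correlation, and its median was 0.12 without the 12 h array. Blood cell markers had a median of -0.03 with 0 of 13 passing.

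**Figure D2:**
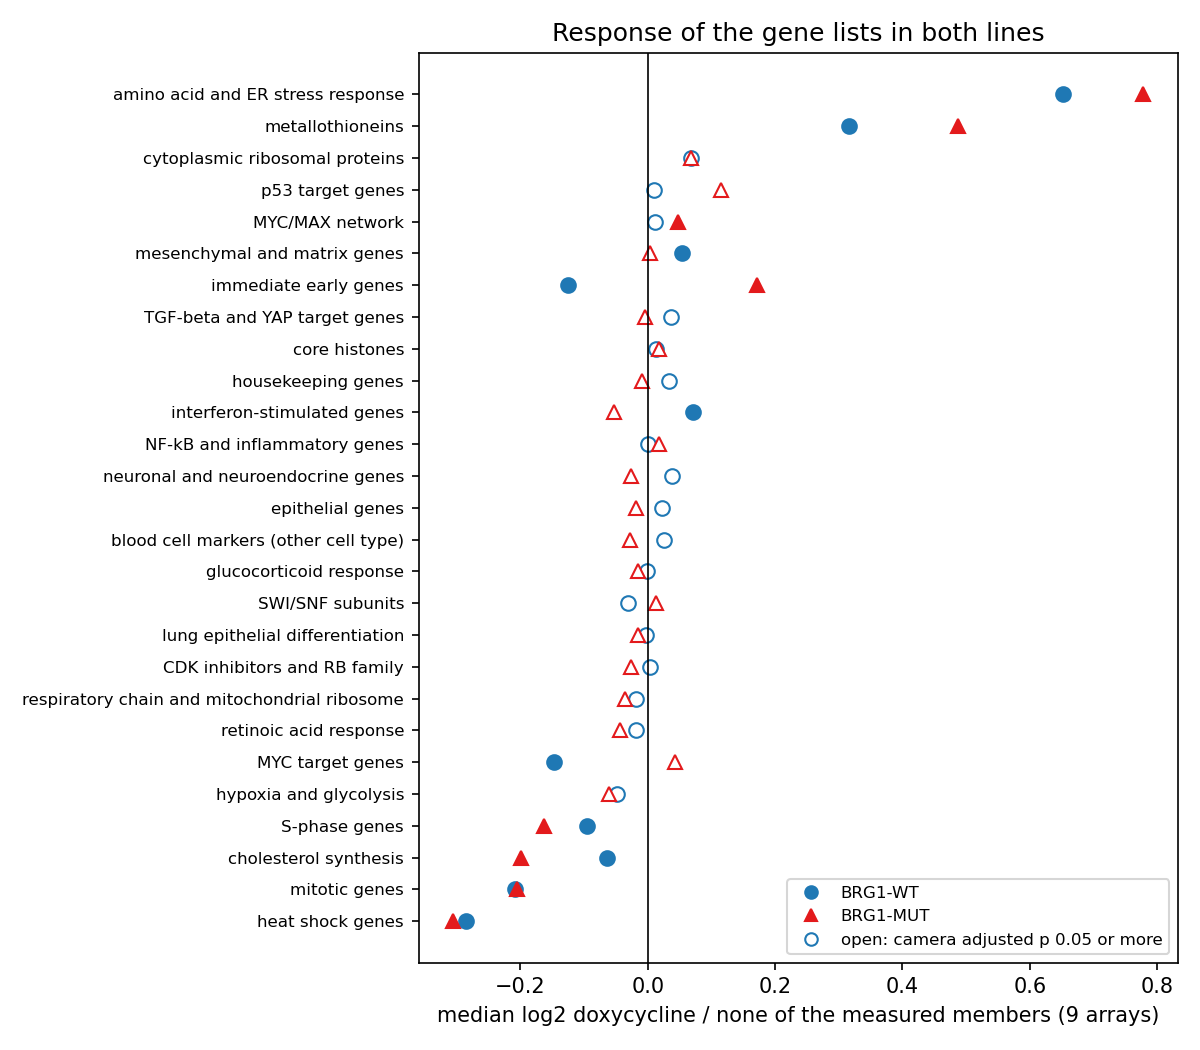
Each pair of points is the median log2 ratio of doxycycline over none (x axis) over the measured members of 1 gene list (y axis) in BRG1-WT and in BRG1-MUT, 9 arrays, with open symbols where the camera adjusted p missed the threshold. The amino acid and ER stress response list lies farthest to the right, at 0.65 in BRG1-WT and 0.78 in BRG1-MUT.

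The responses of both lines shared direction for most genes that passed in both. Of these, 266 were higher in both lines (34.9 for independent lists), 164 lower in both (23.0), 8 higher in BRG1-WT and lower in BRG1-MUT (26.2) and 42 the reverse (30.6). Across 27115 genes the responses correlated at r = 0.452 (Spearman's rho 0.364), where genes are not independent. Their covariance was 0.0135, against 0.000876 from the error that both share through the dye intercept.

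The test of BRG1-WT minus BRG1-MUT asks which responses differ between the lines. The kind of BRG1 cannot be told apart in it from other differences between the lines. Doxycycline itself cancels if both lines respond to it alike. IL11 responded more in BRG1-WT by 1.53 ± 0.087 (SE, adjusted p = 0.00507), and its response in BRG1-MUT was 0.11, 0.32 and 0.04 at 6, 12 and 24 h. KNL1 (1.37 ± 0.14, adjusted p = 0.0165) and ITGA9 (0.89 ± 0.099, adjusted p = 0.021) also lay higher in BRG1-WT, as did KRT86 (0.96 ± 0.094, adjusted p = 0.0152). EGR1, an immediate early transcription factor, lay lower by -1.28 ± 0.12 (adjusted p = 0.0143), HES1 by -0.91 ± 0.075 (adjusted p = 0.0103) and FOS by -0.87 ± 0.088 (adjusted p = 0.016). SMARCA4 itself differed by -0.26 ± 0.15 (adjusted p = 0.431), which missed the threshold. That value compares fold changes, not levels. On slide 2 at 24 h its brightest probe's raw signal with and without doxycycline was 24373 and 3532 in BRG1-WT. In BRG1-MUT it was 65807 and 6614.5. On slide 3 it was 7368 and 3789 (BRG1-WT 12 h replicate 2) against 25174 and 11203 (BRG1-MUT 24 h replicate 1). Levels were not tested, and the amount of SMARCA4 RNA cannot be told apart from the kind of BRG1.

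Further genes with a higher response in BRG1-WT were SHROOM3 (0.86), TDRD10 (0.85), the cytosolic DNA sensor adaptor STING1 (0.78), ZNF329 (0.76), ADAP2 (0.76), the semaphorin and VEGF co-receptor NRP1 (0.70) and CYP2B6 (0.70). ANXA3 met the rule too, but untreated BRG1-MUT cells were not well above background for it on any array, so no fold is given. Genes with a lower response were the splicing factor PRPF19 (-1.07), TRIOBP (-1.02), the zinc transporter SLC39A7 (-0.87), the histone methyltransferase NSD3 (-0.80), the histone demethylase KDM4A (-0.78) and the sulfate transporter SLC26A2 (-0.74). POTEE (-1.07), POTEB3 (-0.98), POTEG (-0.94) and POTED (-0.86) are near-identical relatives and uncertain.

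Immediate early genes lay lower in BRG1-WT as a list, with a median difference of -0.24 and 5 of 24 lower (11 adjusted over the list alone; camera adjusted p = 3.4e-07, adjusted p = 0.641 with an estimated correlation), ATF3 (-0.54 ± 0.085) and DUSP1 (-0.55 ± 0.072) among them. The amino acid and ER stress list differed by -0.19, with 3 of 26 lower (2 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.00406, adjusted p = 0.641 with an estimated correlation). At 24 h this list's median was 0.86 in BRG1-WT (1 array) and 0.78 in BRG1-MUT, the other way round. Within slides its median difference was 0.034 on slide 2 (24 h arrays) and -0.27 on slide 3. MYC target genes (-0.16), metallothioneins (-0.14), cholesterol synthesis genes (0.15) and interferon-stimulated genes (0.072) passed camera at 0.00096, 0.0315, 0.0142 and 0.026, with 0 members passing in the first 3 of these lists, also adjusted over the list alone, and 1 in the interferon list. Their adjusted p with an estimated correlation was 0.714, 0.735, 0.641 and 0.641. Without the BRG1-MUT 12 h array no member of the 6 lists passed limma's threshold, while camera still called all 6 (immediate early median -0.18, stress median -0.24). Without the BRG1-WT 24 h array 3 immediate early and 6 stress genes were lower (stress median -0.31), and without the BRG1-WT 6 h array 1 stress gene was higher and 1 lower (median -0.066). In the last of these fits camera gave 0.234 for the stress list, 0.393 for metallothioneins and 0.472 for cholesterol synthesis genes, and without the BRG1-WT 24 h array 0.180 for interferon-stimulated genes. SPARC lay higher in BRG1-WT by 0.65 ± 0.084 (adjusted p = 0.0289) and the hypoxia gene NDRG1 by 0.57 ± 0.075 (adjusted p = 0.03), while the Hippo pathway kinase LATS2 lay lower by -0.62 ± 0.087 (adjusted p = 0.0333).

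A total of 428 genes differed, 104 higher and 324 lower in BRG1-WT, and with turned signs 1588, among them 98 of the 104 and 302 of the 324. Within slide 2 (24 h arrays) IL11 differed by 1.99, KNL1 by 0.34, HES1 by -1.02 and FOS by -0.85, and within slide 3, where times differ, by 1.58, 1.41, -0.075 and -0.26. These genes were picked on the same arrays, so their signs within slides are no separate test. The count was 44 with slide as a block (without the BRG1-WT 6 h array), 2 without BRG1-MUT 12 h replicate 2 (EGR1 -0.82, KNL1 0.85, HES1 -0.61, CYP2B6 0.42, ZNF329 0.50 and LATS2 -0.40, none passing), 33 and 90 without BRG1-WT 12 h replicate 2 and 1, 4119 and 8560 without BRG1-MUT 24 h replicate 2 and 1, and 0 by limma without the dye intercept, where 1722 genes had an unadjusted p < 0.05. Without the BRG1-WT 24 h array EGR1 was -0.83, KRT86 0.59 and NRP1 0.36, and without the BRG1-WT 6 h array SLC39A7 was -0.48.

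In BRG1-MUT, LMNB1 was -1.62 ± 0.085 at 6 h (n = 2), 2.41 ± 0.13 at 12 h (n = 1) and 1.27 ± 0.085 at 24 h (n = 2), with an adjusted p = 0.000512 over the times. The nuclear noncoding RNA MALAT1 went from -1.03 to 2.35 and 2.21 (adjusted p = 0.00048), DLST, an enzyme of the TCA cycle, from -1.77 to 2.27 and 1.86 (adjusted p = 0.000689), and the co-chaperone DNAJC7 from -1.08 to 1.44 and 1.76 (adjusted p = 0.00127). GAS5, a noncoding RNA, was 0.01, -0.22 and 1.80 (adjusted p = 0.00235). In BRG1-WT, GDF15 was 0.57 at 6 h, 1.49 at 12 h and 3.56 ± 0.15 at 24 h, and EGR1 was -0.32, -0.38 and -1.70 ± 0.18.

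At single times, BRG1-WT at 12 h had NUPR1 (1.89), SMARCA4 (1.85) and TRIB3 (1.72) as the largest rises and MED13L (-0.96), the surface protein LY6K (-0.86) and the G-protein regulator RGS2 (-0.83) as the largest falls. At 24 h GDF15, NUPR1 (2.38) and TRIB3 (2.29) led upward, and LY6K (-2.02), EGR1 and RGS2 (-1.56) downward. BRG1-MUT at 6 h had DDIT4 (2.10), SMARCA4 (2.09) and TRIB3 (1.74) above, and DLST and LMNB1 below. MED18, in the treated channel not well above background, was at least 3.15-fold lower there (adjusted p = 0.0109). On BRG1-MUT 6 h replicate 1, which was left out, its array ratio was 0.056 as labelled, which shows no such fall in either direction. At 12 h LMNB1, MALAT1 and DLST led upward, with KNL1 (-2.28), SCD5 (-1.40) and ZNF329 (-1.12) lowest. At 24 h they were TRIB3 (2.91), GDF15 (2.27) and DDIT3 (2.21), with LY6K (-1.63), DEPP1 (-1.47) and the importin IPO7 (-1.31) lowest.

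Between lines at 24 h, 38 genes differed, 8 higher and 30 lower in BRG1-WT, led by IL11 (1.95), KRT86 (1.61) and the dopamine receptor DRD5 (1.38) above and DLST (-2.38), MALAT1 (-2.29) and DNAJC7 (-2.14) below. In BRG1-WT 199 genes passed at 12 h and 117 at 24 h, and in BRG1-MUT 710 at 6 h, 623 at 12 h and 3846 at 24 h. By limma 0 genes passed in BRG1-WT at 6 h (1 array; 2133 at an unadjusted p under 0.05, and 12 with turned signs) and 0 over the times in BRG1-WT (3034 at an unadjusted p under 0.05, and 12 with turned signs). Over the times in BRG1-MUT 862 genes passed, and 2621 with turned signs. With turned signs the counts were 774 and 2966 in BRG1-WT at 12 and 24 h, 2585, 4244 and 4744 in BRG1-MUT at 6, 12 and 24 h, and 436 between lines at 24 h.

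**Figure D3:**
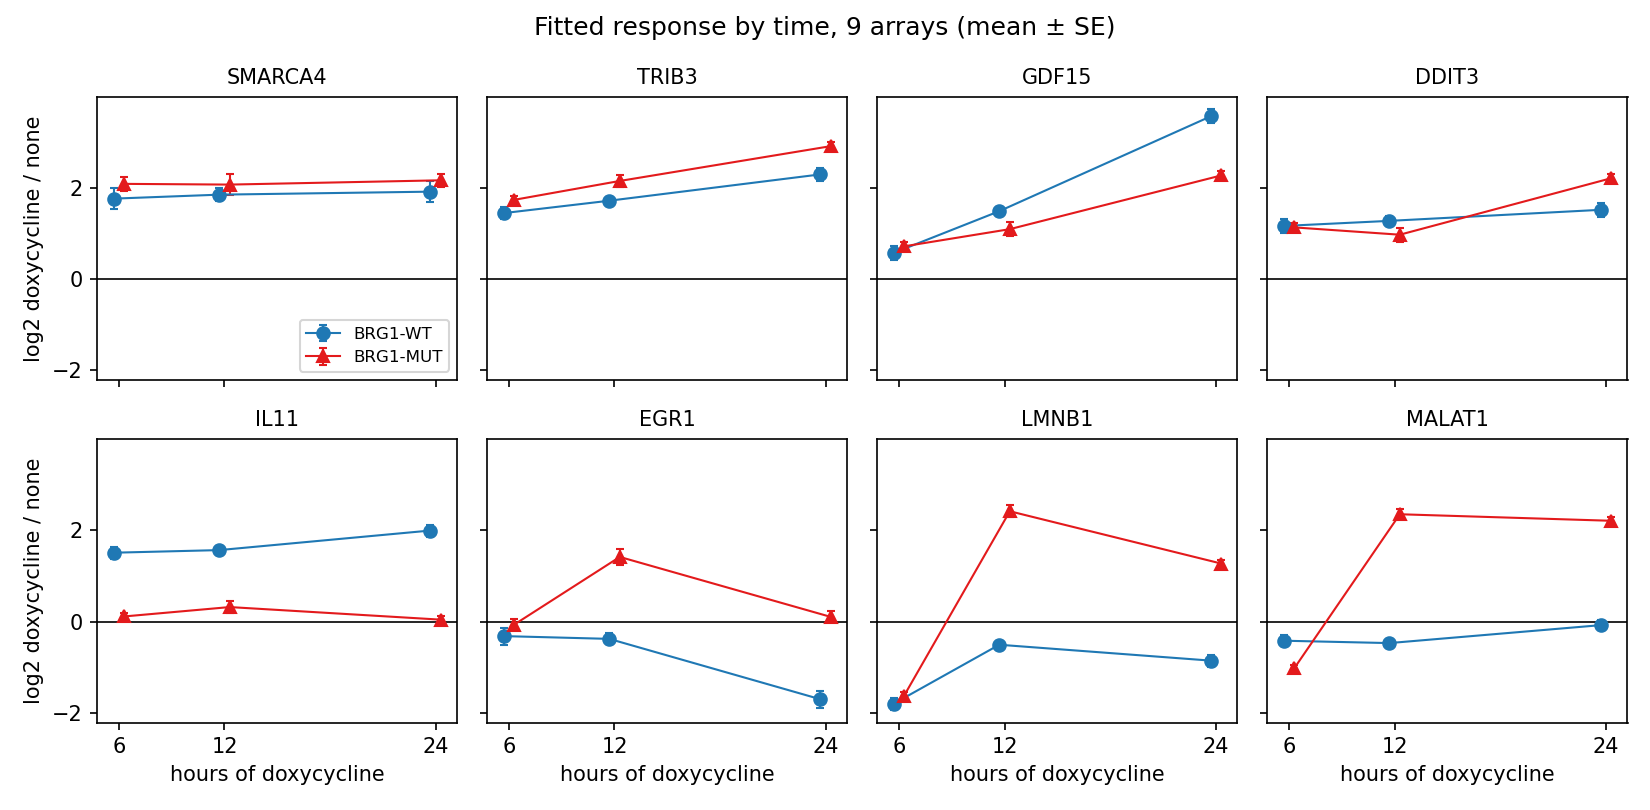
Points are the log2 ratio of doxycycline over none (y axis) at 6, 12 and 24 h (x axis, hours) for 8 genes in BRG1-WT and BRG1-MUT, 9 arrays, with the SE of the fit as bars. GDF15 reaches 3.56 in BRG1-WT at 24 h, and LMNB1 and MALAT1 in BRG1-MUT change sign between 6 and 12 h, from -1.62 to 2.41 and from -1.03 to 2.35. Each BRG1-WT time lies on a slide of its own, so time and slide cannot be told apart there.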

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

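The fits of 9 arrays and with turned signs were chosen only after the SMARCA4 values had been seen. So were the tests of why SMARCA4 fell on 3 arrays. The other tests of explanations were set before their results, except that the slide test was judged by a stricter rule than the one set.

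The test of the difference itself was read in the fit of 9 arrays. There the response to doxycycline differed between BRG1-WT and BRG1-MUT over the mean of the times for 428 genes. By limma the count was 0 with all arrays as labelled. In the 9 arrays it was 0 without the dye intercept and 0 with the replicate block. With the arrays of each group kept together, 3 of 10 splits of the groups gave as many as 428. By camera 6 gene lists differed, with adjusted p = 0.641 to 0.735 with an estimated correlation and 0.131 or more by fry. Of the 428 genes that differed, the naming rule for this comparison took 24, of which the 23 with a measured level in both lines are given below. The list medians of BRG1-WT minus BRG1-MUT were -0.24 for immediate early genes, -0.19 for the amino acid and ER stress response, -0.16 for MYC target genes, -0.14 for metallothioneins, 0.15 for cholesterol synthesis and 0.072 for interferon-stimulated genes. Genes with a higher response in BRG1-WT were IL11 (1.53), KNL1 (1.37), KRT86 (0.96), ITGA9 (0.89), SHROOM3 (0.86), TDRD10 (0.85), STING1 (0.78), ZNF329 (0.76), ADAP2 (0.76), NRP1 (0.70) and CYP2B6 (0.70). Genes with a lower response were POTEE (-1.07), PRPF19 (-1.07), TRIOBP (-1.02), POTEB3 (-0.98), POTEG (-0.94), HES1 (-0.91), FOS (-0.87), SLC39A7 (-0.87), POTED (-0.86), NSD3 (-0.80), KDM4A (-0.78) and SLC26A2 (-0.74). EGR1 differed by -1.28 and was not taken, because the rule set the array ratios with the dye effect left in, and its BRG1-WT 6 h ratio of 0.014 lay above its BRG1-MUT 6 h mean of -0.068.

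At 24 h the lines differed for IL11 (1.95), KRT86 (1.615), DRD5 (1.38), DLST (-2.38), MALAT1 (-2.29) and DNAJC7 (-2.14). Over the times in BRG1-MUT 862 genes differed, and the naming rule took 5 of them, whose 12 h minus 6 h values were 4.04 for LMNB1, 4.03 for DLST, 3.37 for MALAT1, 2.52 for DNAJC7 and -0.23 for GAS5. The last of these reached its high value at 24 h.

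SMARCA4 fell with doxycycline on 3 arrays of slide 1 whose labels put doxycycline in Cy5. A fall of SMARCA4 alone is argued against by the amino acid and ER stress list, whose highest median on these arrays as labelled was -0.48, while it lay above 0 on the other 9. A dye bias of the probe is argued against by the gap of 3.59 in log2 Cy5 over Cy3 between the 3 arrays and the nearest other array labelled forward. Exchanged dye labels remain open and had the values they need once the dye effect was removed. The highest correlation of these arrays with an array of their own group was then -0.374 across genes other than SMARCA4. Before removal it was 0.458, so this reading rests on a dye effect set by other arrays. No biological explanation was tested, and the dyes of these arrays may be recorded the wrong way round, which is a hypothesis.

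Of the 26 amino acid and ER stress genes 16 rose in BRG1-WT and 21 in BRG1-MUT (camera adjusted p = 0.182 and 0.260 with an estimated correlation). Dye bias is argued against by the swapped arrays, on which the lowest list median was 0.75 before and 0.60 after the dye effect was removed. An effect of doxycycline itself cannot be told apart from an effect of the transgenes, because no array held cells without a transgene, and the responses of the lines correlated at 0.452 across genes. That both transgenes raise these genes stays open too and is untested.

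Immediate early and MYC target genes had lower list medians in BRG1-WT than in BRG1-MUT by camera at the preset correlation (adjusted p = 0.641 and 0.714 with an estimated correlation). Of their members 5 of 24 and 0 of 40 passed limma's threshold, and 11 and 0 adjusted over the list alone. That the single BRG1-MUT 12 h array makes the difference in the list medians is argued against by the fit over 6 and 24 h, in which the larger adjusted p of both lists was 0.000769, with medians of -0.16 and -0.14. The calls of single members do hang on that array, since without it none of the 5 immediate early genes passed limma's threshold. Within both slides the differences of both lists lay below 0, which the criterion set beforehand counted against a slide effect. That criterion took no account of spread. Judged against the spread, a slide effect cannot be told apart. On slide 3 the within-slide differences of -0.058 and -0.054 lay within 1 SD between the BRG1-MUT arrays (0.088 and 0.20). On slide 2 they were -0.16 and -0.13 against the 24 h array, and -0.28 and -0.11 against all 3 BRG1-MUT arrays, whose SDs were 0.17 and 0.057. The kind of BRG1 stays open, as a hypothesis. Each transgene was measured in its own line, so other differences between the lines cannot be told apart from it.

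Other choices of sign or grouping of the same arrays were counted for each number of genes. As labelled, the counts of 0 by limma are reached by every choice, so these choices are no test of chance. In BRG1-WT all 16 of 16 sign choices gave as many as the 0 genes, and the highest other choice gave 22, with the array labelled 24 h replicate 1 opposite to the rest. In BRG1-MUT, with 0 genes as labelled, all 64 of 64 gave as many and the highest other gave 3841, the choice that sets the arrays labelled 12 h replicate 1 and 6 h replicate 1 opposite to the rest, which points to a structure of the arrays. For the difference between lines, with 0 genes, 100 of 100 groupings gave as many, the highest other 3.

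With 9 arrays, the real signs gave 671 genes in BRG1-WT, 1 of 8 choices gave as many, and the highest other gave 53; the choices are too few for a share under 0.05. In BRG1-MUT the real signs gave 4638, 1 of 16 choices gave as many, and the highest other gave 2030, with the 6 h arrays turned; these too are too few. The difference between lines had 428 genes, 2 of 100 drawn groupings gave as many, the highest other gave 791 and did not follow the slides. Most of these groupings part the replicate arrays that set the spread, so they are no test of chance. With the arrays of each group kept together, 3 of 10 splits of the groups gave as many as 428, and the highest other gave 1550, with both 6 h groups and BRG1-WT 12 h against the rest. These splits are too few for a share under 0.05.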

How the results depend on the processing

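The fits without the 3 arrays, with their sign turned, and every alternative run within those fits were added after the data had been seen, and the cause of the changes below was not tested unless fewer arrays or a stricter limit explains them. Of 296 results for named genes, 292 kept their sign in every setting other than the labelled directions. As labelled none of the 296 kept its call. Among the other settings most calls were lost without the dye intercept (275), with the replicate block (170) and with Agilent's log ratios (160). Turned signs lost 7 calls. Signal over background limits dim genes such as MED18 and ANXA3.

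As labelled, without background correction 1 gene passed in BRG1-MUT 24 h. Agilent's log ratios and the series matrix values each gave 1 gene in BRG1-WT, 1 in BRG1-WT 6 h, 1 in BRG1-MUT 24 h and 1 over the times in BRG1-WT. Scaling between arrays gave 1 in BRG1-MUT 24 h. Median centring gave 9 lists in BRG1-WT against 4. Array weights gave 2 genes in BRG1-WT 6 h, 5379 in BRG1-WT 12 h and 4810 in BRG1-MUT 6 h. Slide as a block gave 5 genes in BRG1-WT 6 h and 9 lists for BRG1-WT minus BRG1-MUT, and slide as a random block 8 lists, against 5. An estimated correlation and fry each gave 0 lists in BRG1-WT, 0 in BRG1-MUT (against 7) and 0 for the difference.

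Without the 3 arrays SMARCA4 passed in BRG1-WT (1.84) and BRG1-MUT (2.11). Genes passing were 671 in BRG1-WT, 4638 in BRG1-MUT, 428 for the difference, 199 and 117 in BRG1-WT 12 h and 24 h, 710, 623 and 3846 in BRG1-MUT 6, 12 and 24 h, 38 for the difference at 24 h and 862 over the times in BRG1-MUT, with 10 lists in BRG1-WT. With the 3 arrays turned SMARCA4 was 1.83 and 2.13, and genes passing were 3245, 7475 and 1588, then 12, 774 and 2966 in BRG1-WT 6, 12 and 24 h, 2585, 4244 and 4744 in BRG1-MUT 6, 12 and 24 h, 436 for the difference at 24 h, and 12 and 2621 over the times in BRG1-WT and BRG1-MUT, with 9 lists in BRG1-WT.

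In the 9 arrays, genes in BRG1-WT, in BRG1-MUT and for the difference, where they moved by over 1.5 times, were as follows. No background correction gave 387 in BRG1-WT and 274 for the difference. Agilent's log ratios and the series matrix values each gave 35, 2967 and 46. Scaling gave 739 for the difference. No dye intercept gave 4, 68 and 0 (0 by limma, with 1722 genes at an unadjusted p < 0.05). Array weights gave 5390 and 2344 in BRG1-WT and for the difference, and equal weight for every array 1227 and 284. A 1.5-fold limit gave 172, 324 and 251. Slide as a block, without the BRG1-WT 6 h array, gave 165, 2441 and 44. An estimated correlation gave 0 lists in each comparison, and fry 2 in BRG1-WT and 0 for the difference.

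The replicate block, with the arrays that the labels do not number as 1 level, gave 0, 2441 and 0 genes in the 9 arrays by limma, with 739 and 783 at an unadjusted p < 0.05 where the count was 0. Both unadjusted counts lie below what chance alone gives on average at that limit among the genes tested. The 2441 equals that with slide as a block. In both fits the BRG1-MUT dye swaps alone set the sum of dye and block on which the BRG1-MUT values rest. Within BRG1-MUT dye and block cannot be told apart, because its forward and swapped arrays lie in different blocks. Deviations of arrays numbered 1 and 2 by the labels (BRG1-MUT 6 and 12 h) correlated at 0.167 over 2 pairs, fewer than are needed to take the numbers as pairs. Both arrays numbered 1 in these pairs were left out of the 9 arrays, because SMARCA4 went against their labels. The correlation therefore cannot show whether arrays of the same number share an effect. With turned signs the block gave 33, 3811 and 0 genes, slide as a block 165, 4017 and 6, and each swap pair averaged 1311, 4681 and 228.

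Leaving out each array in turn, as labelled, gave 2 to 10 lists in BRG1-WT and 3 to 7 for the difference, and 0 genes throughout. In the 9 arrays it gave 22 to 6830 genes in BRG1-WT, 1453 to 12081 in BRG1-MUT and 2 to 8560 for the difference, and 6 to 11 lists in BRG1-WT and 4 to 11 for the difference. Some named values turned sign. TGM2 in BRG1-MUT was -0.0082 with the mean of all probes, HSPE1 in BRG1-WT was 0.015 without the dye intercept, and without BRG1-MUT 12 h replicate 2 FOS and RPS3 in BRG1-MUT were -0.056 and 0.022, the ends of ranges of -0.056 to 0.30 and -0.26 to 0.022 over the arrays left out. With the arrays as labelled, BRG1-MUT 12 h gave -0.15 for DLST, -0.080 for LMNB1 and -0.14 for MALAT1, and the difference at 24 h gave -0.14 for DRD5 and -0.29 for KRT86, since 1 of the 3 arrays belongs to each of these groups. Slide as a random block (no estimate), a fit of 1 line alone and averaged swap pairs (no residual degrees of freedom) were not run in the 9 arrays.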

Other observations

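The fit of 9 arrays used here was chosen after the SMARCA4 values had been seen. Some gene groups that missed camera's threshold still held members that changed. SWI/SNF subunits, with SMARCA4 in the list, had a median of -0.03 in BRG1-WT and 0.01 in BRG1-MUT (camera adjusted p = 0.315 and 0.796), and SMARCA2, the paralogous ATPase and a gene outside the naming rule, measured -0.01 ± 0.12 and -0.01 ± 0.098 (SE). ARID2, a subunit of the PBAF form, fell by 0.51 ± 0.080 in BRG1-MUT (adjusted p = 0.0103). CDK inhibitors and RB family genes had 0 of 10 passing in BRG1-WT (3 higher and 1 lower adjusted over the list alone) and 1 higher and 4 lower in BRG1-MUT, CDKN2C among the latter. CDKN1B measured 0.26 ± 0.064 in BRG1-WT and -0.09 ± 0.053 in BRG1-MUT, with a difference of 0.35 ± 0.077 (adjusted p = 0.0934) that missed the threshold. With turned signs CDKN1B was 0.32 in BRG1-WT and 0.37 for the difference, and both passed limma's threshold (adjusted p = 0.00931 and 0.0255). MYC target genes in BRG1-MUT had a median of 0.04 and a mean of -0.01, with 7 of 40 lower (camera adjusted p = 0.803).

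Of p53 target genes, 2 of 25 rose and 1 fell in BRG1-WT and 6 rose and 4 fell in BRG1-MUT (camera adjusted p = 0.240 and 0.0847, fry 0.0187 and 0.00708). SESN2, also a stress-response gene, rose by 0.96 ± 0.076 and 1.44 ± 0.063, while the exonuclease gene AEN fell by 0.38 ± 0.063 and 0.22 ± 0.052. Hypoxia and glycolysis genes (medians -0.05 and -0.06, camera adjusted p = 0.312 and 0.0513) went both ways. The growth factor VEGFA rose by 0.66 ± 0.092 and 0.83 ± 0.076, whereas ADM fell by 0.61 ± 0.074 and 0.43 ± 0.061. NF-kB and inflammatory genes (medians 0.00 and 0.02, camera adjusted p = 0.920 and 0.796) included TNFAIP2, which rose by 0.62 ± 0.073 and 0.52 ± 0.061, beside the fall of BIRC3. In the TGF-beta and YAP target list (medians 0.04 and -0.00, camera adjusted p = 0.804 and 0.796), LATS2 fell by 0.43 ± 0.072 in BRG1-WT. Of the glucocorticoid list (medians -0.00 and -0.02, camera adjusted p = 0.920 and 0.796), ANGPTL4 fell by 0.54 ± 0.070 and 0.23 ± 0.058. MT2A, in the same list, rose by 0.57 ± 0.066 in BRG1-MUT. With turned signs ANGPTL4 in BRG1-MUT was -0.22 and missed limma's threshold (adjusted p = 0.102). Of the retinoic acid list (medians -0.02 and -0.04, camera adjusted p = 0.920 and 0.796), DHRS3, a retinal reductase, rose by 0.45 ± 0.068 and 0.39 ± 0.056.

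Neuronal and neuroendocrine genes had medians of 0.04 and -0.03 (camera adjusted p = 0.352 and 0.833). The granins CHGB and SCG2 rose in BRG1-MUT by 0.61 ± 0.072 and 0.53 ± 0.069. Lung epithelial differentiation genes had medians of -0.00 and -0.02 (0.804 and 0.853). In BRG1-MUT FOXA1 fell by 0.41 ± 0.050, while LAMP3 rose by 0.47 ± 0.081 and ABCA3 by 0.34 ± 0.077. Epithelial genes had medians of 0.02 and -0.02 (camera adjusted p = 0.179 and 0.833), and KRT18 rose by 0.25 ± 0.059 in BRG1-MUT. Mesenchymal and matrix genes had a median of 0.00 in BRG1-MUT (0.833), with SPARC at -0.00 ± 0.058. Interferon-stimulated genes had a median of -0.05 in BRG1-MUT (0.520), and the MYC/MAX network 0.01 in BRG1-WT (0.528). Cytoplasmic ribosomal proteins (0.07 and 0.07, camera adjusted p = 0.0561 and 0.0514), the respiratory chain and mitochondrial ribosome (-0.02 and -0.04, 0.365 and 0.541), core histones (0.01 and 0.02, 0.744 and 0.833) and housekeeping genes (0.03 and -0.01, 0.875 and 0.796) missed the threshold too. Of the ribosomal proteins 5 of 25 were higher and 1 lower in BRG1-MUT. Some of these results hang on 1 array. Without the BRG1-MUT 12 h array camera gave 0.000343 in BRG1-MUT for ribosomal proteins, with no member passing limma's threshold, and 0.0126 for hypoxia and glycolysis genes. Without the BRG1-WT 6 h array it gave 0.0188 in BRG1-WT for ribosomal proteins, and without the BRG1-WT 24 h array 0.000683 for core histones (median 0.15). The transferrin receptor gene TFRC, in the housekeeping list, fell by 0.36 ± 0.062 and 0.59 ± 0.051.

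LMNB1, DLST and DNAJC7 were low at 6 h in both lines. At 6 h LMNB1 measured -1.80 in BRG1-WT and -1.62 in BRG1-MUT, DLST -1.67 and -1.77, and DNAJC7 -1.36 and -1.08. The BRG1-WT values rest on 1 array and missed the threshold (adjusted p = 0.107, 0.107 and 0.126). By 24 h they measured -0.86, -0.52 and -0.38 in BRG1-WT and 1.27, 1.86 and 1.76 in BRG1-MUT. The BRG1-WT times lie on different slides, so a change with time cannot be told apart from slide in that line.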
